A study of Mus musculus with 24 samples.

How the data were processed

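RNA sequencing libraries were made from mouse bone marrow-derived macrophages, which are primary macrophages grown from marrow precursors. Cells came from wild-type C57BL/6 mice (WT) or from mice with a knockout of Ninj1 (KO), and were either kept in media only or stimulated with Pam3, the common short name of the synthetic TLR1/TLR2 ligand Pam3CSK4. The labels give 4 groups of 6 libraries, named here WT_media, KO_media, WT_Pam3 and KO_Pam3. Replicate numbers follow the order of deposition and pair nothing between groups. The labels do not say whether the 6 libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Dose and duration of the stimulation are not given in the sources used here. Per the labels' protocols, polyA RNA was purified on columns with DNase digestion, libraries were made with a TruSeq RNA v2 kit, which does not mark strand, and sequencing was single-end with 50 bp reads on a HiSeq4000.

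The submitters' processing notes name the aligner GSNAP and the genome build GRCm38, without versions or settings. Per the file headers, the count column holds the number of reads that align uniquely to each gene model, with no normalization by the authors. The second column holds RPKM values adjusted by a size factor, per the file headers. The counts entered every test, and the RPKM values served only as a check of the count columns. Reads that align to several places are absent from unique counts, so closely related genes can lose reads or share them, and values of Mndal, Ifi206, Ifit3, Ifit3b, Tgtp2, Ly6a, the histocompatibility genes and the T-cell receptor segments are uncertain for that reason. Reads of overlapping or antisense genes cannot be told apart without strand. Each file lists 52636 gene models by Ensembl identifier. GENCODE mouse release 21, on GRCm38, gave a symbol and coordinates for 52403 of them, and the remaining 233 held 0.0196% of the reads. All 522 symbols of the gene lists were found.

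Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, TMM normalization, a mean per group, all 24 libraries in 1 fit so that the equal-sized groups share an estimate of the spread). The filterByExpr filter left 14435 genes. The biological coefficient of variation was 8.21%. No covariate was fitted, because the labels give no batch, animal or pairing. Comparisons were KO against WT in media, KO against WT after Pam3, Pam3 against media in each genotype, and the interaction, which is the Pam3 response in KO minus that in WT. A gene passed the test at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM, the counts scaled to TMM-adjusted library sizes, as mean ± SD with n = 6 libraries per group. CPM are not corrected for gene length, so they compare groups and not genes.

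Gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, and p-values were adjusted over 135 set tests together. Camera compares the genes of a list with all other tested genes. An estimated correlation between genes and fry, which tests whether the genes of a list move one way on balance, were alternatives. The 28 lists were inflammasome and pyroptosis, apoptosis and necroptosis, TLR receptors and adaptors, NF-kB targets and feedback, cytokines, chemokines, interferon-stimulated genes, antimicrobial effectors and prostaglandin, glycolysis and hypoxia, cholesterol synthesis, LXR targets, unfolded protein and amino acid stress, antioxidant NRF2 targets, lysosome and phagocytosis, macrophage identity, MHC and antigen presentation, cell cycle, cell adhesion and membrane repair, markers of granulocytes, dendritic cells, lymphocytes, mast cells and basophils, erythroid cells and megakaryocytes, and stromal and endothelial cells, mitochondrial transcripts, sex-linked genes, C57BL/6 substrain genes, and genes within 5 Mb of Ninj1. Some genes stand in more than 1 list. The sex-linked list had 1 tested member and no set test. The tests, lists, most alternatives and rule for named genes were fixed before the data were examined.

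Ninj1, Ninj2, Nlrp3, Casp1, Casp4, Pycard, Gsdmd, Il1a, Il1b, Il18, Tlr2, Tnf, Il6, Nnt and the 5 sex-linked genes were always named. Each comparison of 2 groups added the 8 largest fitted rises and 8 largest fitted falls among genes that passed the test, had a mean of at least 20 counts per library in the higher group and had all 6 libraries of one group above all 6 of the other. For the interaction the 5 largest in each direction were taken with the same count minimum and no condition on separation. Predicted gene models were passed over. Up to 4 members per list with the smallest adjusted p could also be named. Gpr137b, and the granulocyte markers compared one by one in the closing tests, were named after their values were seen.

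Whether the Pam3 response differed in size was asked with a total least squares slope of the KO on the WT log2 fold changes over genes, with a jackknife SE over libraries. Library composition was compared with 2-sided exact permutation tests over the 924 splits of 6 against 6, 16 tests adjusted together. The 60 pairs of libraries within groups differed by a chi-square of 2.54 to 142 per degree of freedom, above sampling noise, so no library counted as a duplicate. Libraries held 31302011 to 40663152 counted reads. A count of 0 allows an upper limit of 3 counts at 95% confidence, which is 0.0627 to 0.111 CPM per library. Such limits cover counting error only, because reads are not independent molecules.

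The code was tested on simulated counts in which 200 genes were changed. It recovered 89.7% of 2-fold, 70.0% of 1.5-fold and 56.5% of 1.25-fold changes for KO against WT in media (14292 genes), and 88.9%, 73.9% and 37.5% after Pam3 (14300 genes). For Pam3 against media it recovered 91.3%, 78.6% and 48.0% in WT (14270 genes), and 94.0%, 74.7% and 53.5% in KO (14248 genes). For the interaction it recovered 74.6%, 67.2% and 23.6% (14303 genes). False calls were 5.84%, 3.68%, 0.694%, 6.25% and 6.90% of the calls in these 5 simulations. For Pam3 against media the simulated groups differed in the 200 genes alone, while most genes changed in the data. Those rates therefore do not describe the real Pam3 comparisons. Simulated libraries varied independently, and none was made to stand apart from its group.

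Alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter or at least 50 counts on average, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, a fit of only the 12 libraries compared, 1 surrogate variable (sva 3.50.0), glmTreat against a 2-fold change, stricter thresholds, genes on the sex chromosomes left out, thinned counts and each library left out in turn. Leaving out WT_Pam3 replicate 5 and KO_media replicate 1 together, and repeating the set tests without each of them, was chosen after seeing the data. A covariate for Y-linked transcripts was not fitted, because libraries of both genotypes hardly held any.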

Results

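To ask how macrophages without NINJ1, a membrane protein of plasma membrane rupture in lytic cell death, differ in gene expression at rest and after a bacterial lipopeptide mimic, polyA RNA was sequenced from 24 libraries of bone marrow-derived macrophages, 6 for each combination of genotype (WT or Ninj1 KO) and treatment (media or Pam3). Totals of counted reads did not differ past the test between groups. Treatment dominated the data, with 91.8% of the variance of log2 CPM on the first principal component and 1.63% on the second. After Pam3 the 10 most abundant genes took a smaller share of reads (WT 13.9% ± 0.234 to 9.98% ± 1.07, KO 13.6% ± 0.286 to 9.29% ± 0.176, SD, n = 6, exact permutation adjusted p = 0.00577 for both, from an exact p of 0.00217, the smallest that 6 against 6 can give). Fewer genes were detected after Pam3 with the same exact permutation p, 19610 ± 230 against 18130 ± 105 in WT and 19420 ± 120 against 18390 ± 194 in KO (n = 6). The share of mitochondrial transcripts fell with Pam3 at that exact permutation p too, from 0.628% to 0.435% in WT and from 0.553% to 0.414% in KO. Between genotypes, KO_media held a smaller share of mitochondrial transcripts than WT_media (0.553% ± 0.0354 against 0.628% ± 0.0175, n = 6, exact permutation adjusted p = 0.00990). KO_Pam3 had a smaller share in the top 10 genes than WT_Pam3 (adjusted exact p = 0.0260), a difference carried in large part by WT_Pam3 replicate 5, at 12.2% against 9.49% to 9.60% in the other 5 WT_Pam3 and 9.15% to 9.61% in the KO_Pam3 libraries. KO_Pam3 had more detected genes (adjusted exact p = 0.0423), a difference of 260 that was 170 with counts thinned to the smallest library. WT_Pam3 replicate 5 stood apart from its group in mitochondrial reads as well (0.336%).

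Ninj1 RNA was lower in every KO library than in every WT library of the same treatment. The gene (ENSMUSG00000037966, chromosome 13, positions 49187485 to 49196244 of GRCm38) stood at 307 ± 15.7 CPM in WT_media and 167 ± 9.68 CPM in KO_media, and at 810 ± 176 CPM in WT_Pam3 and 429 ± 25.7 CPM in KO_Pam3 (SD, n = 6). The KO over WT log2 fold change was -0.88 (SE 0.0874, adjusted p = 7.33e-07) in media and -0.92 (SE 0.0872, adjusted p = 4.05e-07) after Pam3, with 6 of 6 libraries lower each time. Ninj1 rose with Pam3 by 1.40 (SE 0.0881) in WT and 1.36 (SE 0.0883) in KO on the log2 scale, and the responses did not differ past the test (interaction -0.04, adjusted p = 0.922). Counts cover the whole gene model and the labels do not say which part was deleted, so the remaining reads say nothing about protein. The direction fits the genotype labels in all 24 libraries. Its paralog Ninj2 was near the limit of detection, at 0 to 0.0985 CPM. Xist, the long noncoding RNA of the inactive X chromosome, was present in all 24 libraries at 233 to 796 CPM, while the Y-linked genes Kdm5d and Eif2s3y had 0 counts, Uty 1 count and Ddx3y 27 counts over all libraries. A count of 0 allows up to 0.0627 to 0.111 CPM per library. This goes against the male label of the WT libraries, and KO libraries carry no sex label. Xist did not differ past the test in any comparison (KO over WT in media -0.25, SE 0.151, adjusted p = 0.554). Nnt, which C57BL/6J carries with a deletion, was low in all libraries at 0.134 to 0.750 CPM.

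Among genes of the inflammasome pathway, which senses cytosolic danger and leads to gasdermin D pores, Nlrp3, Casp1, Casp4, Gsdmd and Il18 rose with Pam3 in both genotypes, while the whole list did not pass the set test in either. Nlrp3, the sensor, went from 74.6 ± 1.92 to 1778 ± 195 CPM in WT and from 75.2 ± 3.18 to 1763 ± 25.3 CPM in KO. Casp1, the protease that matures IL-1 family cytokines, rose by 2.17 (SE 0.0590) in WT and 1.94 (SE 0.0585) in KO on the log2 scale. Casp4, which senses cytosolic lipopolysaccharide, rose by 3.90 and 3.51, Gsdmd by 2.05 and 1.83, and Il18 by 3.72 and 3.67. Pycard, the adaptor ASC, did not pass the test in WT (0.13, adjusted p = 0.169) or KO (-0.00, adjusted p = 0.996). With library size only it was called lower in WT (-0.39, adjusted p = 0.000289, and from 0.000289 to 1 over the alternatives). None of Nlrp3, Casp1, Casp4, Gsdmd, Pycard, Il18 and Il1b differed between genotypes past the test at either treatment. WT_Pam3 replicate 5 lay apart from its group for Nlrp3, Casp1, Casp4, Gsdmd and Pycard. For Il1b that library stood at 5142 CPM, within the KO_Pam3 range of 4841 to 5403 CPM. The other WT_Pam3 libraries held 3963 to 4460 CPM of Il1b, below every KO_Pam3 library. The missing call of Il1b after Pam3 therefore does not show equal levels in the genotypes. Il1a, an alarmin of the IL-1 family, was lower in KO_media (1.21 ± 0.0825 against 0.813 ± 0.312 CPM, log2 -0.58, SE 0.160, adjusted p = 0.0458), and this call ended when nearly any single library was left out. Of the 19 tested members of the inflammasome and pyroptosis list, 1 rose and 1 fell in KO_media (Mefv, the pyrin sensor, and Il1a; 3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.151), and none changed after Pam3 (0 adjusted over the list alone, adjusted p = 0.766).

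**Figure D1:**
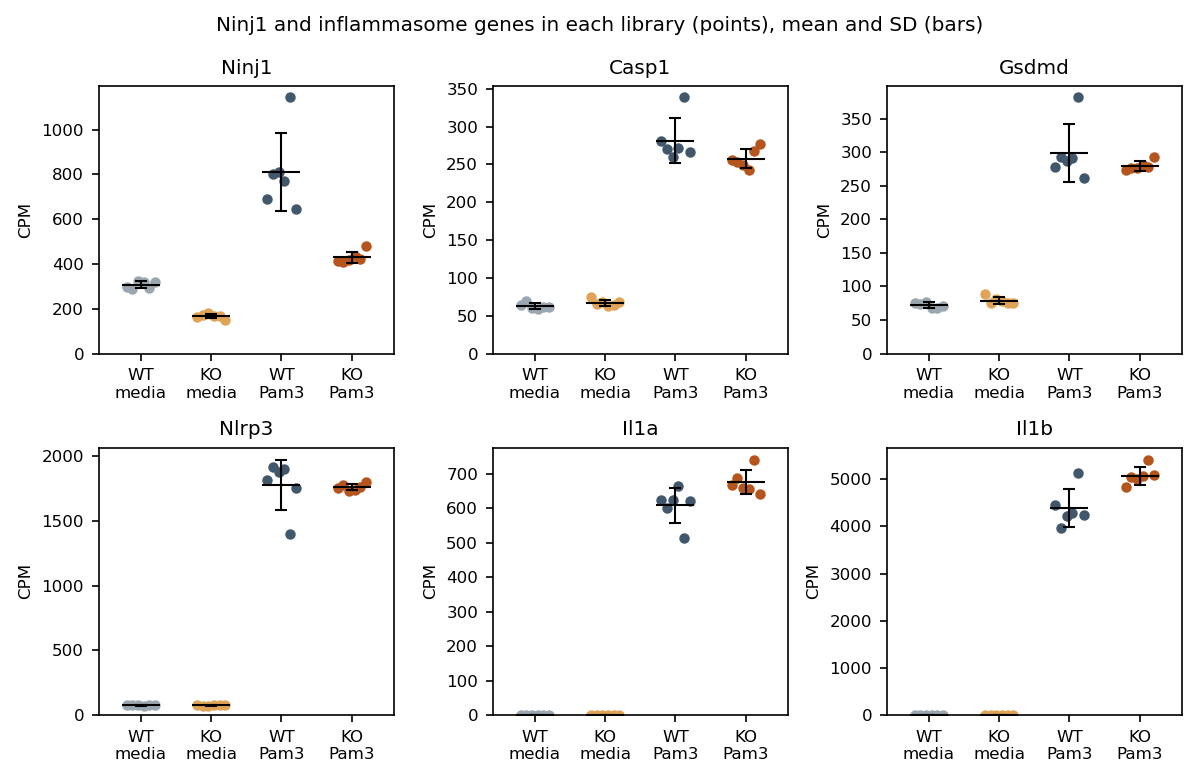
CPM of Ninj1, Casp1, Gsdmd, Nlrp3, Il1a and Il1b in the 24 libraries (1 point each), by group, with the mean as a line and SD as bars (n = 6). Ninj1 lies lower in KO at both treatments (307 against 167 CPM in media), while the 5 other genes separate by treatment.

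Interferon-stimulated genes were higher in KO than in WT macrophages in media. Of 34 tested members of that list, 27 rose and 0 fell (33 rose adjusted over the list alone), with a median log2 fold change of 0.60. Camera gave an adjusted p of 5.67e-41 for the list, and adjusted p = 0.0684 with an estimated correlation, because its members vary together between libraries. Irf7, the transcription factor that amplifies type I interferon, rose from 148 ± 13.3 to 261 ± 88.4 CPM (log2 0.82, SE 0.129, adjusted p = 0.000484). Oasl2, an antiviral effector, rose from 131 ± 12.8 to 226 ± 81.1 CPM (log2 0.79, SE 0.127, adjusted p = 0.000570), each with 6 of 6 KO libraries above all WT libraries. Irf9 (0.30) and Rtp4 (0.65) rose as well, also in 6 of 6 libraries. KO_media replicate 1 stood highest, with a list median of 6.93 log2 CPM against 5.77 to 6.28 in the other 5 KO_media libraries and 5.40 to 5.71 in WT_media. Without it 24 members rose.

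Over all tested genes, that list included, 277 rose and 161 fell in KO_media, and 11 of the higher and 5 of the lower genes changed at least 2-fold. Among genes that met the naming rule, rises included Mndal, a p200-family interferon-inducible gene (37.1 ± 10.3 to 91.6 ± 27.9 CPM, log2 1.30, SE 0.211, adjusted p = 0.000570), Ly6a, the surface antigen Sca-1 (17.9 ± 3.07 to 40.7 ± 17.7 CPM, log2 1.19, SE 0.178, adjusted p = 0.000254). Rises also included Synpo (1.29), Ndrg4 (1.04), the interferon-inducible GTPase Tgtp2 (0.98), Ms4a4c (0.97) and Ifit3 (0.97). Capn11, a calpain protease, was at 0.161 ± 0.179 CPM in WT_media and 2.93 ± 2.04 CPM in KO_media (log2 4.16, SE 0.571, adjusted p = 0.000102). Its levels fell into separate clusters within groups, 1.05 to 1.19 CPM in KO_media replicates 1 to 3 and 4.23 to 5.55 CPM in replicates 4 to 6. The WT libraries with any Capn11 count (WT_media 1, 2 and 5, WT_Pam3 1, 5 and 6) were also those with the lowest Mndal within each treatment. Falls under that rule were Mtus2 (2.88 ± 0.438 to 1.32 ± 0.301 CPM, log2 -1.11, SE 0.158, adjusted p = 0.000137), Paqr9 (-0.93), Ninj1 and Mgll, the lipase that degrades monoacylglycerols (17.3 ± 1.49 to 9.52 ± 0.670 CPM, log2 -0.87, SE 0.0773, adjusted p = 1.09e-07). Tmem26 (-0.73), Selenbp2 (-0.73), the adhesion molecule Vcam1 (16.2 ± 1.13 to 10.2 ± 0.739 CPM, log2 -0.67, SE 0.0711, adjusted p = 2.14e-06) and BC021767 (-0.66) fell too. The smallest adjusted p belonged to Gpr137b, a lysosomal membrane protein, which rose from 58.1 ± 1.80 to 89.1 ± 5.34 CPM (log2 0.62, SE 0.0397, adjusted p = 2.26e-10) and was singled out after its values were seen.

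Granulocyte markers also rose as a list in KO_media. Chemokines and their receptors, stromal markers and MHC genes passed upward and mitochondrial transcripts downward with the preset correlation only (adjusted p = 0.0779, 0.159, 0.183 and 0.122 with an estimated correlation). In the chemokine list 6 of 24 members rose and 0 fell (10 rose and 1 fell adjusted over the list alone), among them the monocyte receptors Ccr2 (0.48) and Cx3cr1 (0.70) and the ligands Cxcl16 (0.24) and Cxcl10 (0.53), with a camera adjusted p of 1.64e-07. Of 14 granulocyte markers 4 rose and 0 fell (4 adjusted over the list alone), namely Ngp (12.3 ± 1.17 to 17.9 ± 0.631 CPM, log2 0.54, SE 0.0624, adjusted p = 6.88e-06), S100a8 (0.51), Ltf (0.53) and S100a9 (0.50), each higher in 6 of 6 KO libraries. The granulocyte list had a camera adjusted p of 2.84e-06 and kept its call with an estimated correlation (adjusted p = 0.0197). Of 14 stromal and endothelial markers 7 rose and 0 fell (9 rose and 1 fell adjusted over the list alone), with the collagen chain Col1a2 at 0.75, the matrix protein Sparc at 0.61, Col6a1 at 0.57 and Cxcl12 at 0.62. For the stromal list camera gave an adjusted p of 1.98e-08 (adjusted p = 0.159 with an estimated correlation). Its mean log2 CPM was 3.42 and 3.44 in KO_media replicates 4 and 6, the libraries with the most Capn11, against 2.72 to 2.84 in replicates 1 to 3 and 2.47 to 2.76 in WT_media. Replicate 5, with Capn11 at 4.23 CPM, lay between these. The stromal count became 1 without KO_media 4, KO_media 6 or WT_media 3, and 2 without WT_media 2 or WT_media 6. Of 19 MHC and antigen presentation genes 3 rose and 0 fell (8 rose adjusted over the list alone), the peptide transporter Tap1 (0.45), B2m (0.19) and Tapbp (0.21), with a camera adjusted p of 1.97e-06 and adjusted p = 0.183 with an estimated correlation. This MHC count became 1 without KO_media 1, WT_media 3 or WT_media 5, and 10 without WT_Pam3 5. Of 10 mitochondrial transcripts 0 rose and 2 fell (4 fell adjusted over the list alone), mt-Cytb (-0.20) and mt-Nd4 (-0.17), with a camera adjusted p of 2.40e-05 and adjusted p = 0.122 with an estimated correlation. The mitochondrial count became 5 without WT_Pam3 5, and 1 without any of WT_media 1 to 5, KO_media 2 to 6, WT_Pam3 2 to 4 or KO_Pam3 1, 2, 3, 5 and 6.

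Smaller shifts passed the set test in 3 further lists in media, all upward. For NF-kB targets and feedback 2 of 24 rose and 0 fell (6 rose adjusted over the list alone), the inhibitor Nfkbie (0.26) and Tnip3 (0.27), at an adjusted p of 0.000499 and adjusted p = 0.223 with an estimated correlation. Antimicrobial effectors had 2 of 23 higher and 2 lower (5 and 2 adjusted over the list alone), with the siderophore-binding Lcn2 (0.57) and the lectin Clec4e (0.39) up and the metal transporter Slc11a1 (-0.17) and arginase Arg1 (-0.89) down, at adjusted p = 0.00180 and adjusted p = 0.351 with an estimated correlation. That call ended without KO_media 1 and with fry. In the unfolded protein and amino acid stress list 1 of 23 rose (1 adjusted over the list alone), the folate enzyme Mthfd2 (0.34), at adjusted p = 0.00420 and adjusted p = 0.265 with an estimated correlation. Without WT_Pam3 5 the higher members were 7 of the NF-kB list, 5 antimicrobial effectors and 3 of the stress list, and antimicrobial effectors had 1 higher without WT_media 3, 5 or 6 or KO_media 5. The remaining lists did not pass. Apoptosis and necroptosis had the nucleic acid sensor Zbp1 (0.85) higher and Bcl2 (-0.47) lower of 24, the same adjusted over the list alone (adjusted p = 0.210). TLR receptors and adaptors had 2 of 23 higher, Tlr2 (85.6 ± 5.18 to 99.3 ± 5.38 CPM, 0.21) and Myd88 (0.19), and 1 lower, the scavenger receptor Cd36 (-0.34), with 3 and 1 adjusted over the list alone (adjusted p = 0.0826). Cytokines had 1 of 20 higher, the macrophage growth factor Csf1 (0.38), also adjusted over the list alone (adjusted p = 0.143). Lysosome and phagocytosis had Ctss (0.19) higher and Msr1 (-0.20) and Atp6v0d2 (-0.20) lower of 28, the same adjusted over the list alone (adjusted p = 0.186). Macrophage identity had 1 of 25 higher, Fcgr1 (0.33), with 4 higher and 5 lower adjusted over the list alone (adjusted p = 0.599). Cell adhesion and membrane repair had Itgal (0.36) higher and Vcam1 and Itgax (-0.23) lower of 25 (3 and 2 adjusted over the list alone, adjusted p = 0.857), with median and mean below 0 and a test direction above it. Dendritic cell markers had Fscn1 (0.68) and Dpp4 (0.58) higher and Itgax lower of 12 (3 and 1 adjusted over the list alone, adjusted p = 0.222). NRF2 targets had 1 of 17 lower, Mgst1 (-0.20), also adjusted over the list alone (adjusted p = 0.273).

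In 8 lists no member passed the test in media by edgeR over all genes. These were glycolysis and hypoxia (adjusted p = 0.967, 1 lower adjusted over the list alone, median above 0 and mean below), cholesterol synthesis (0.179), LXR targets (0.718, 1 higher adjusted over the list alone, median below 0 and mean above), cell cycle (0.0565), lymphocytes (0.277), mast cells and basophils (0.662), erythroid cells and megakaryocytes (0.0710) and substrain genes (0.273). Apart from the 2 exceptions named, the count adjusted over the list alone was 0 in each, as it was for the sex-linked list, which had Xist as its tested member. Among 46 genes within 5 Mb of Ninj1, 2 rose in KO_media, Gm34084 (0.68) and the chromatin factor Jarid2 (0.29), and 5 adjusted over the list alone (adjusted p = 0.760, median below 0 and mean above). The counts of higher and lower genes moved with single libraries, to 154 and 84 without WT_media 3 and to 658 and 616 without WT_Pam3 5, and the lower count to 107, 95 and 100 without KO_media 1, 4 or 5.

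**Figure D2:**
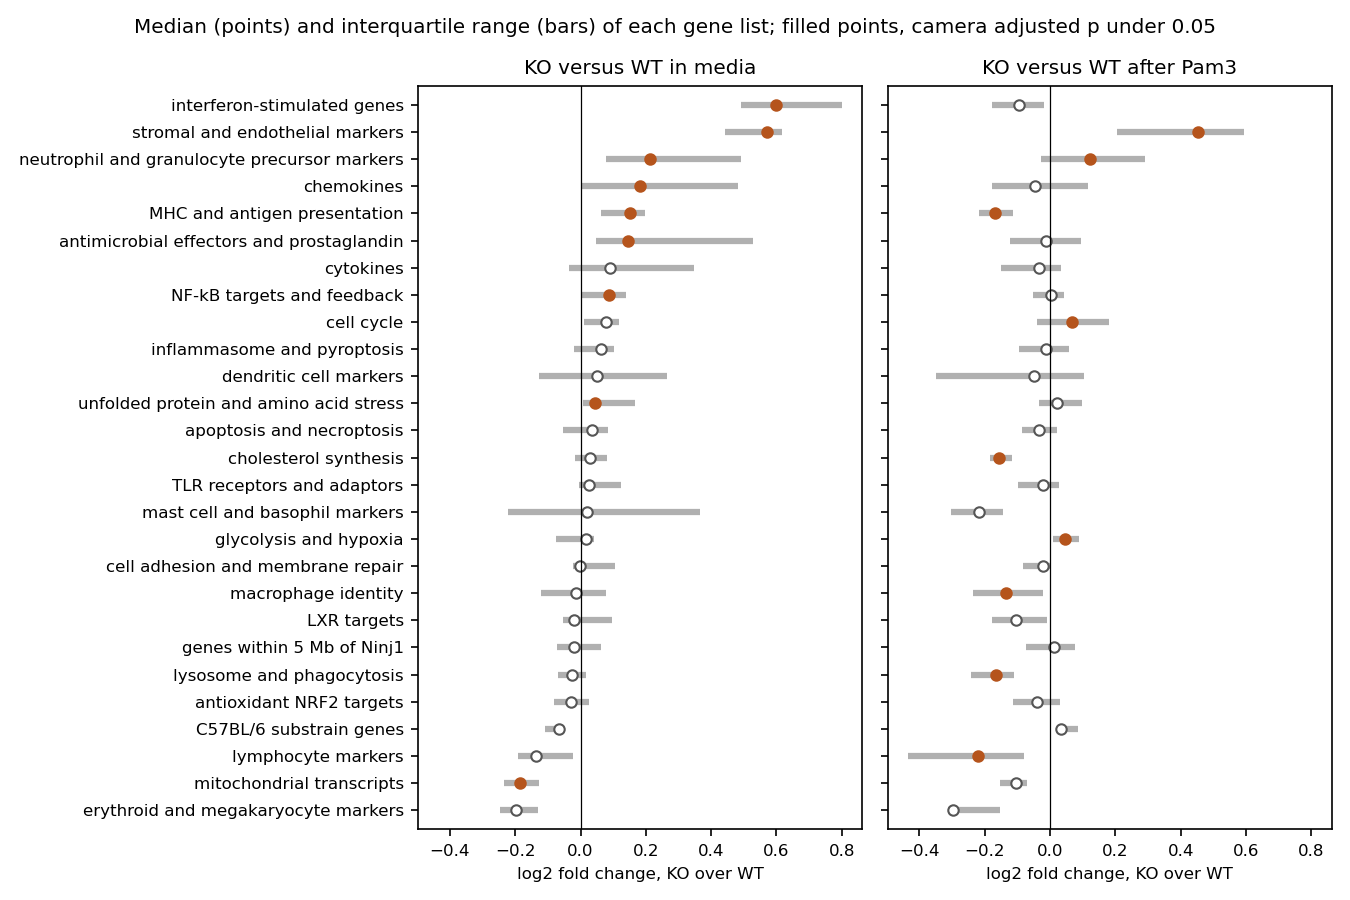
Median log2 fold change of KO over WT for 27 gene lists in media and after Pam3, with bars from the lower to the upper quartile of the members and filled points where the camera adjusted p is under 0.05. The interferon-stimulated list has the highest median in media (0.60) and lies at -0.09 after Pam3, and stromal markers lie above 0 in both (0.57 and 0.45).

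After Pam3, KO macrophages had lower lysosomal and phagocytic transcripts than WT macrophages, and the interferon-stimulated genes no longer differed past the test. Of 28 lysosome and phagocytosis genes 12 fell and 0 rose (21 fell and 1 rose adjusted over the list alone). Mertk, the receptor for engulfing apoptotic cells, fell from 34.0 ± 4.10 to 22.0 ± 1.82 CPM (log2 -0.63, SE 0.0631, adjusted p = 7.11e-07). Gpnmb (-0.27), the sphingolipid activator Psap (-0.25) and the proton pump subunit Atp6v0d2 (-0.31) fell too, each lower in 6 of 6 KO libraries. Camera gave an adjusted p of 1.23e-14 for this list, and the call held with an estimated correlation (adjusted p = 0.0198). In the macrophage identity list 6 of 25 fell and 1 rose (11 and 1 adjusted over the list alone), with Mertk and the glycoprotein Cd68 (-0.28) down and the integrin Itgam (0.17) up, at adjusted p = 7.60e-05, which also held with an estimated correlation (adjusted p = 0.0169). In the same comparison stromal and granulocyte markers passed upward and lymphocyte markers downward with the preset correlation only (adjusted p = 0.330, 0.223 and 0.0556 with an estimated correlation). Of 21 cholesterol synthesis genes 6 fell and 0 rose (14 fell adjusted over the list alone), with the sterol sensor partner Insig1 (381 ± 13.6 to 301 ± 16.2 CPM, log2 -0.34, SE 0.0428, adjusted p = 1.47e-05), Lss (-0.23), Sc5d (-0.18) and Mvd (-0.33), each lower in 6 of 6 libraries. That list had a camera adjusted p of 2.84e-09 and adjusted p = 0.0813 with an estimated correlation. Its count was 12 without WT_Pam3 5 and 3 with library size only.

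Across all genes 189 rose and 397 fell in KO_Pam3, 11 and 4 of them at least 2-fold, and the median size of a called change was 0.28 on the log2 scale. The balance depended on settings. Library size only gave 412 higher and 220 lower, or 65.2% higher in place of 32.3%, and no filter gave 183 and 183, while DESeq2 size factors (190 and 402) and upper-quartile scaling (234 and 326) kept more genes lower. The counts depended on settings too, with 63 higher and 114 lower in a fit of only the 12 libraries compared, which lost 419 of the 586 calls, and 422 and 861 with 1 surrogate variable. Of 47 calls of Gpr137b and of list members with the smallest adjusted p here, 27 ended in the fit of 12 libraries. Mndal again rose (95.8 ± 36.7 to 196 ± 8.04 CPM, log2 1.03, SE 0.207, adjusted p = 0.00331), with WT_Pam3 libraries in separate clusters at 58.8 to 65.4 CPM (replicates 1, 5 and 6) and 127 to 133 CPM (replicates 2, 3 and 4). Other rises were Has1, a hyaluronan synthase (3.27 ± 1.04 to 5.83 ± 0.434 CPM, log2 0.84, SE 0.145, adjusted p = 0.00124) and the cadherin Cdh11 (0.74). So were the myeloid receptor Trem1 (2.02 ± 0.261 to 3.34 ± 0.499 CPM, log2 0.72, SE 0.117, adjusted p = 0.000345), Plat (0.72), Trem3 (0.74), Kirrel (0.84) and Capn11 (0.0574 ± 0.0650 to 0.738 ± 0.397 CPM). The calls of Capn11 (adjusted p = 0.0399), Kirrel (0.0454) and Trem3 (0.0343) ended when any of several libraries was left out, and that of Plat (0.0186) without KO_Pam3 4. Gpr137b was higher here as well (55.3 ± 2.37 to 84.7 ± 2.72 CPM, log2 0.62, SE 0.0402, adjusted p = 2.94e-10). Falls under the naming rule were Mtus2 (2.91 ± 0.865 to 1.26 ± 0.175 CPM, log2 -1.20, SE 0.175, adjusted p = 0.000100), Mgll (5.75 ± 0.972 to 3.03 ± 0.246 CPM, log2 -0.92, adjusted p = 2.46e-06) and Ninj1. Next came Pyroxd2 (-0.81), the dynein assembly factor Dnaaf3 (-0.78), Asb2 (-0.78), the kinesin Kif5c (-0.73) and the nonclassical MHC gene H2-M2 (51.7 ± 2.64 to 32.5 ± 1.88 CPM, log2 -0.67, SE 0.0667, adjusted p = 7.11e-07). The count of higher genes was 125 without WT_Pam3 2, 116 without KO_Pam3 3 and 106 without KO_Pam3 4, and without WT_Pam3 5 the counts were 352 and 826.

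MHC and antigen presentation had 3 of 19 lower (8 adjusted over the list alone), the class II chaperones H2-DMb1 (-0.32) and H2-DMa (-0.29) and the class II transactivator Ciita (-0.35), at adjusted p = 4.21e-05 and adjusted p = 0.239 with an estimated correlation. This count became 5 without WT_Pam3 5 and 1 without KO_Pam3 2, 3 or 5, KO_media 2 to 6, or WT_media 2, 4, 5 or 6. Stromal markers had 4 of 14 higher (8 higher and 1 lower adjusted over the list alone), Col6a1 (0.65), Dcn (0.58), Col1a2 (0.60) and Col3a1 (0.56), at adjusted p = 5.78e-05 and adjusted p = 0.330 with an estimated correlation. Their mean log2 CPM was 3.75, 3.85 and 3.81 in KO_Pam3 1, 3 and 4, the KO_Pam3 libraries with the most Capn11 (1.03 to 1.22 CPM), and 3.30 to 3.35 in KO_Pam3 2, 5 and 6, while WT_Pam3 lay at 2.75 to 3.39. The stromal count became 1 without KO_Pam3 1, 3 or 4 and 2 without WT_Pam3 4. Granulocyte markers had 2 of 14 higher (3 adjusted over the list alone), Ngp (0.43) and S100a8 (0.29), at adjusted p = 0.0151 and adjusted p = 0.223 with an estimated correlation, and 1 without any of KO_Pam3 1, 2, 4 and 6 or WT_Pam3 1, 2, 3, 4 and 6. Lymphocyte markers had 2 of 10 lower (3 adjusted over the list alone), Ighm (40.7 ± 4.77 to 29.0 ± 1.36 CPM, -0.49) and Cd4 (-0.40), at adjusted p = 0.00244 and adjusted p = 0.0556 with an estimated correlation. Glycolysis and hypoxia had 1 of 21 higher, Ndrg1 (0.15), also adjusted over the list alone, at adjusted p = 0.00934 and adjusted p = 0.428 with an estimated correlation, and not with fry. Cell cycle passed upward at adjusted p = 0.0413 with 0 of 34 members called over all genes or adjusted over the list alone, a median of 0.07 and adjusted p = 0.535 with an estimated correlation. That call ended with upper-quartile scaling, with library size only, with fry and without KO_media 1.

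Interferon-stimulated genes had 0 of 34 called in KO_Pam3 (0 adjusted over the list alone, 2354 genes in all at an unadjusted p under 0.05 by edgeR), a median of -0.09 and an adjusted p of 0.171. The set test passed downward with library size only and without KO_media 1. Most other lists did not pass either. Apoptosis and necroptosis had 2 of 24 lower, including Bid (-0.19), the same adjusted over the list alone (adjusted p = 0.2997). In the TLR list 0 of 23 passed, also adjusted over the list alone (0.811). NF-kB targets had Cd83 (-0.23) lower of 24, also adjusted over the list alone (0.820, median above 0 and mean below). Cytokines had Lif (0.63) higher and Il15 (-0.33) and Il12a (-0.27) lower of 20, with 2 and 2 adjusted over the list alone (0.650). Chemokines had 3 of 24 higher, including the receptor Ccr2 (0.37), and 2 lower, Ccrl2 (-0.23) and Cxcl9 (-0.40), with 5 and 8 adjusted over the list alone (0.850). Antimicrobial effectors had the haem oxygenase Hmox1 (-0.17) lower of 23, with 2 higher and 2 lower adjusted over the list alone (0.850, median and mean below 0 and a test direction above it). The stress list had Trib3 (0.73) higher and Atf3 (-0.18) lower of 23, with 1 and 2 adjusted over the list alone (0.367). NRF2 targets had Mgst1 (-0.34) and Hmox1 lower of 17, with 3 lower adjusted over the list alone (0.0837). Adhesion had Itga5 (0.16) higher and Vcam1 (-0.43) lower of 25, with 2 and 1 adjusted over the list alone (0.473). Dendritic cell markers had Zbtb46 (0.94) higher of 12, with 1 higher and 4 lower adjusted over the list alone (0.568). Mitochondrial transcripts had mt-Cytb (-0.17) and mt-Nd4 (-0.18) lower of 10, also adjusted over the list alone (0.0535). LXR targets (0.123, 2 lower adjusted over the list alone), mast cells (0.345), erythroid cells and megakaryocytes (0.280, 1 lower adjusted over the list alone) and substrain genes (0.605) had 0 members called, and those without a count given also 0 adjusted over the list alone. Near Ninj1, Fgd3 (0.17) and Secisbp2 (0.12) rose and Rnf144b (-0.33) and Dtnbp1 (-0.30) fell of 46, with 5 and 5 adjusted over the list alone (0.507, median above 0 and mean below).

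Between the 2 genotype comparisons, which share no library, 102 genes were called in both, 38 higher in both, 61 lower in both and 3 in opposite directions. Independent lists of these sizes would share 3.63 higher and 4.43 lower genes. The labels do not say whether both comparisons drew on the same animals or cultures, which could raise the overlap. Mndal levels split the WT libraries, and Capn11 levels the KO libraries, at both treatments. Shared sources therefore cannot be set aside, and the overlap is not that of comparisons known to be independent. Over all 14435 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.233.

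**Figure D3:**
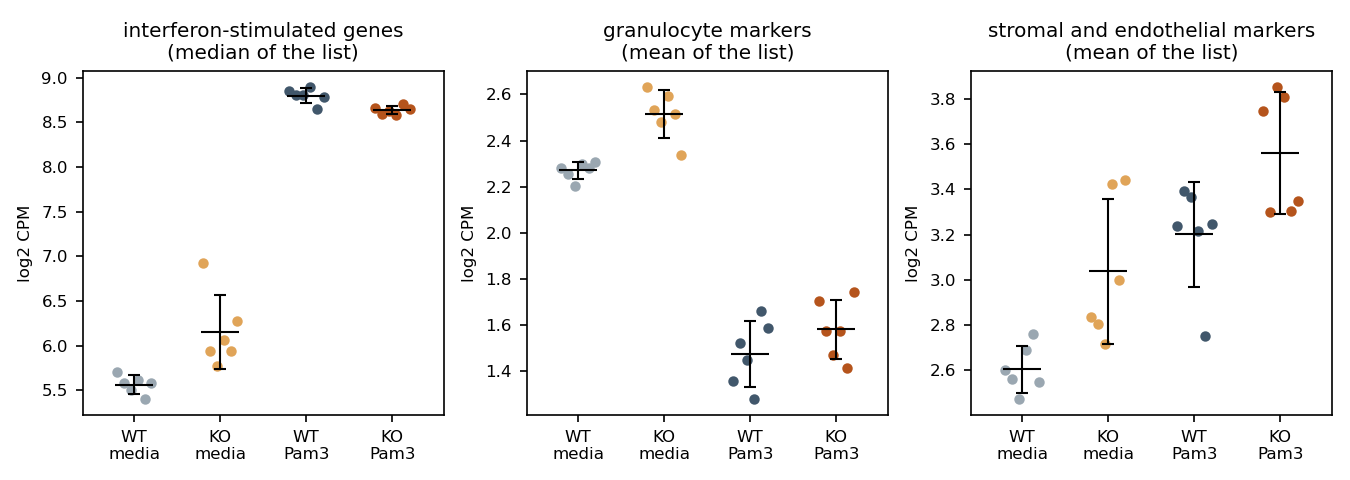
Log2 CPM per library (1 point each) of the interferon-stimulated list median, the granulocyte marker mean and the stromal marker mean, by group, with mean and SD (n = 6). In media the 6 KO libraries lie above all WT libraries for the interferon list (5.77 to 6.93 against 5.40 to 5.71) and the granulocyte markers, and the stromal mean is split within KO groups.

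Pam3 remodelled the transcriptome of both genotypes toward inflammation. In WT 5859 genes rose and 6376 fell, 84.8% of those tested, and 2621 and 3628 of them changed at least 2-fold, while KO had 5803 higher and 6470 lower (85.0%), with 2583 and 3645 at least 2-fold. Tnf, the early inflammatory cytokine, went from 10.5 ± 1.13 to 7341 ± 574 CPM in WT and from 10.7 ± 1.40 to 6574 ± 223 CPM in KO (n = 6). Il1b went from 0.561 ± 0.177 to 4385 ± 404 CPM in WT and from 1.06 ± 0.799 to 5071 ± 184 CPM in KO. Ptgs2, the inducible cyclooxygenase, went from 0.273 ± 0.115 to 2877 ± 665 and from 0.559 ± 0.0649 to 3015 ± 267. Acod1, which makes itaconate, went from 2.93 ± 0.933 to 11940 ± 390 and from 5.80 ± 5.46 to 11840 ± 220. The neutrophil chemokine Cxcl2 went from 0.824 ± 0.186 to 3322 ± 292 CPM in WT and from 1.37 ± 0.572 to 3013 ± 158 CPM in KO. All 6 stimulated libraries stood above all 6 unstimulated ones for these genes, and each passed the test (largest edgeR adjusted p = 1.78e-20, for Acod1 in KO). Near the detection limit in media were Il6 (to 301 ± 19.7 and 304 ± 17.6 CPM), Csf3 (to 39.5 ± 5.32 and 47.0 ± 4.66), the microRNA host Mir155hg (to 35.6 ± 3.72 and 36.8 ± 1.71) and the nitric oxide synthase Nos2 (to 387 ± 47.1 and 359 ± 40.8). Shisa3, with 0 counts in WT_media, rose at least 21610-fold there against a limit of 3 counts over the 6 libraries.

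The deepest falls with Pam3 included Fam214a (87.6 ± 4.71 to 0.364 ± 0.132 CPM in WT, log2 -7.89, and -7.55 in KO), the peroxisomal transporter Abcd2 (34.4 ± 1.83 to 0.231 ± 0.114 CPM, -7.18, and -7.66) and Rasgrp3, a Ras activator (156 ± 6.62 to 1.248 ± 0.449 CPM, -6.95, and -7.25), with edgeR adjusted p of 7.84e-27 or less in each. Galnt9 went from 2.43 ± 0.256 to 0.00561 ± 0.0137 CPM and BC106179 from 3.84 ± 0.201 to 0.0171 ± 0.0188 CPM in WT, and in KO Zbtb16 from 2.35 ± 0.349 to 0.0102 ± 0.0249 CPM and Asb10 from 1.39 ± 0.2999 to 0.00507 ± 0.0124 CPM. In WT, against a limit of 3 counts over the group, Slc25a27 was at least 76.6-fold lower, Smim10l2a at least 73.0-fold and Fam227a at least 34.5-fold. In KO the T-cell receptor segments Trav13n-4 and Trav14n-3 were at least 36.6-fold and 33.1-fold lower. Ninj1 was among the genes that rose, Nnt fell in WT (0.548 ± 0.129 to 0.235 ± 0.0389 CPM) and KO (0.489 ± 0.119 to 0.255 ± 0.113 CPM), and Tlr2, a receptor for Pam3, rose by 3.52 in WT and 3.28 in KO on the log2 scale. Directions depend on scaling. The median log2 fold change of all genes was -0.05 in WT and -0.07 in KO with TMM, -0.58 and -0.56 with library size only, and -0.25 in both with upper-quartile scaling. With library size only 3584 genes rose and 9055 fell in WT (28.4% higher) and 3685 rose and 8935 fell in KO (29.2% higher), against 47.9% and 47.3%. Xist, which did not pass in KO (0.05, adjusted p = 0.769), was called lower with library size only (-0.43, adjusted p = 0.01001).

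As lists, inflammatory genes rose in both genotypes. Counts adjusted over the list alone equalled those over all genes unless given. All 24 NF-kB targets and feedback genes rose in each genotype, with medians of 3.66 in WT and 3.70 in KO, and examples in the inhibitor Tnip3 (5.75 and 5.48), the adhesion molecule Icam1 (5.03 and 4.78) and the manganese superoxide dismutase Sod2 (5.69 and 5.60), at an adjusted p of 3.36e-13. Of 20 cytokines 19 rose and 1 fell in each (1.13e-07). In the adhesion and membrane repair list 21 of 25 rose and 2 fell in each (1.41e-05), led by Icam1, the fibronectin receptor subunit Itga5 (3.66 and 3.75) and Itgal (5.25 and 5.17). These 3 lists held their calls with an estimated correlation (adjusted p = 0.0155, 0.0169 and 0.00449 in both genotypes). Together with granulocyte markers in media and the lysosome and macrophage identity lists after Pam3 they are all the set calls that held. Chemokines rose in 19 of 24 and fell in 4 in WT, and 20 and 4 in KO (6.60e-06, and adjusted p = 0.122 with an estimated correlation in both), with Ccl3 at 6.75 and 6.76. Interferon-stimulated genes rose in 34 of 34 in WT with a median of 2.99 and in 33 of 34 in KO with a median of 2.18 (1.31e-10 and 4.99e-09, and adjusted p = 0.415 and 0.444 with an estimated correlation), led by the guanylate-binding proteins Gbp5 (6.94 and 6.36) and Gbp2 (5.59 and 4.90). Antimicrobial effectors rose in 21 of 23 and fell in 1 in each (1.89e-08, and adjusted p = 0.0779 with an estimated correlation), with the prostaglandin E synthase Ptges at 8.31 and 8.07. The single antimicrobial fall in WT became 2 without WT_Pam3 5.

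Metabolic and growth genes moved too. Cholesterol synthesis rose in 20 of 21 and fell in 1 in each genotype (4.48e-08 and 1.09e-07, and adjusted p = 0.122 with an estimated correlation in both), with Lss at 2.23 and 2.02. Glycolysis and hypoxia rose in 17 and fell in 2 of 21 in WT (18 and 2 adjusted over the list alone) and 18 and 3 in KO (0.000363 and 0.000204, and adjusted p = 0.239 with an estimated correlation in both), with the glucose transporter Slc2a1 at 3.04 and 3.26. NRF2 targets rose in 14 and fell in 2 of 17 in each (0.000886 and 0.00162, and adjusted p = 0.265 and 0.299 with an estimated correlation), with glutathione reductase Gsr at 3.68 and 3.86. MHC genes rose in 17 and fell in 1 of 19 in each (18 and 1 adjusted over the list alone in WT, 5.16e-05 and 0.000451, and adjusted p = 0.239 and 0.330 with an estimated correlation), with Cd274, the ligand PD-L1, at 4.14 and 3.91. Cell cycle genes fell in 27 and rose in 4 of 34 in WT and 28 and 3 in KO (0.000527 in both, and adjusted p = 0.393 with an estimated correlation), with the cyclin Ccnd1 at -4.40 and -4.45. TLR receptors and adaptors rose in 15 and fell in 6 of 23 in WT and 15 and 5 in KO (0.0170 and 0.0133, and adjusted p = 0.460 and 0.444 with an estimated correlation), with the inhibitory kinase Irak3 at 4.12 and 4.13. Apoptosis genes rose in 16 and fell in 5 of 24 in WT, and 16 and 4 in KO (0.0239 in both, and adjusted p = 0.239 with an estimated correlation), but with library size only in 11 and 11, and 12 and 11. The stress list rose in 15 and fell in 6 of 23 in WT and 13 and 7 in KO (0.0312 and 0.0429, and adjusted p = 0.428 and 0.444 with an estimated correlation), calls that ended without WT_Pam3 5. Lysosome genes fell in 18 and rose in 6 of 28 in WT and 21 and 7 in KO (0.0464 and 0.00999, and adjusted p = 0.510 and 0.444 with an estimated correlation), and the WT call ended with DESeq2 size factors.

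The remaining lists did not pass for Pam3 against media. Inflammasome genes rose in 11 and fell in 5 of 19 in WT (0.0612) and 12 and 6 in KO (0.0655), against 9 and 9 in both with library size only. LXR targets had 5 up and 5 down of 12 in WT (0.716) and 5 and 6 in KO (0.820), with medians below 0 and means above in both. Macrophage identity had 11 and 12 of 25 in WT (0.599) and 8 and 13 in KO (0.365), with Cd14 at 3.43 and 3.29. Granulocyte markers had 3 up and 10 down of 14 in each (0.262 and 0.186). Dendritic cell markers had 3 and 7 of 12 in WT (3 and 8 adjusted over the list alone) and 3 and 6 in KO (0.471 in both). Lymphocyte markers had 5 and 5 of 10 in each (0.754 and 0.669, medians below 0 and means above). Mast cell markers had 1 and 1 of 4 in each (0.819 and 0.992, with the median below 0 and the mean above it in KO). Erythroid and megakaryocyte markers had 4 up of 6 in each (0.172 and 0.179), among them the platelet chemokine Pf4 (1.44 and 1.26). Stromal markers had 5 up and 1 down of 14 in WT (5 and 0 adjusted over the list alone) and 5 and 3 in KO (0.484 and 0.565, median below 0 and mean above in KO), turning to 3 up and 9 down and 3 and 10 with library size only. Mitochondrial transcripts had 0 called of 10 in WT (0.978, median above 0 and mean below) and mt-Nd1 up in KO (0.811, 0 adjusted over the list alone), against 9 down in each with library size only. All 3 substrain genes fell in each genotype (0.186 and 0.231). Of 46 genes near Ninj1, 15 rose and 25 fell in WT (0.273) and 17 and 24 in KO (0.303), with the kinase Syk at 2.43 and 2.46.

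The Pam3 responses of the genotypes were close in size. The set test of the difference passed for interferon-stimulated, MHC, lysosomal and cholesterol synthesis genes with the preset correlation, but adjusted p = 0.130, 0.0649, 0.0684 and 0.0779 with an estimated correlation. Over 14435 genes, which are not replicates, the slope of the KO on the WT response was 0.983 (jackknife SE 0.00929, and 0.979 to 0.991 with a library left out) with a Pearson r of 0.986. Of 12235 genes called in WT, 11537 (94.3%) were called with the same sign in KO and 5 with the opposite sign. In the test of the difference itself, 25 genes had a more positive and 85 a more negative response in KO. Of these genes, 49 were also called between genotypes in media and 54 after Pam3. Of 34 interferon-stimulated genes 10 had a more negative and 0 a more positive response in KO (32 more negative adjusted over the list alone), with a median difference of -0.73. Of the same 34 genes, 27 were already higher in KO_media, while a lower level in KO after Pam3 was not called. The smaller rise thus goes with a higher start in media. Irf7 differed by -0.83 (SE 0.181, adjusted p = 0.0264), Xaf1 by -0.79, Rtp4 by -0.75 and Ifit3 by -1.18. Ifit3 stood at 42.5 ± 4.35 and 83.1 ± 42.2 CPM in WT_media and KO_media, and at 204 ± 27.7 and 175 ± 10.4 CPM in WT_Pam3 and KO_Pam3. Camera gave an adjusted p of 3.00e-27 for the list and adjusted p = 0.130 with an estimated correlation.

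Under the naming rule, the genes with positive differences were Dio2, which activates thyroid hormone (0.78, SE 0.131, adjusted p = 0.00904), Gpr155 (0.76), Il1a (0.73), Rims3 (0.67) and Lonrf1 (0.55). Those with negative differences were Cd101 (-1.35), Ifit3, Tgtp2 (-1.12), Ifi206 (-1.04) and Ifit3b (-0.98). Kif5c (-0.64) fell further with Pam3 in KO, and Tlr2 (-0.24, adjusted p = 0.0396) rose less. Calls of Cd101, Ifi206, Ifit3b, Il1a, Rims3 and Tlr2 ended when any of many single libraries was left out, that of Gpr155 without KO_Pam3 3, that of Ifit3 without KO_Pam3 3 or WT_media 3 or 5, and that of Tgtp2 without KO_Pam3 3 or 4 or WT_media 3, 4 or 5. The interferon-list count of 10 became 0 without WT_media 3 or 5, 1 without KO_Pam3 3, 4 without WT_media 2, 4 or 6, KO_media 6, WT_Pam3 2 or 4 or KO_Pam3 1, 2 or 4, 5 without WT_Pam3 1, 6 without KO_media 4, WT_Pam3 3 or KO_Pam3 5, 19 without KO_media 3, 23 without KO_media 1 and 32 without WT_Pam3 5. The all-gene counts of more positive and more negative responses became 8 and 20 without WT_media 3 or WT_media 5, 8 and 29 without KO_Pam3 3, 12 and 48 without KO_Pam3 2, 12 and 45 without KO_Pam3 4, 15 and 56 without WT_Pam3 2, 12 and 52 without WT_Pam3 4, and 102 and 442 without WT_Pam3 5. The more negative count alone moved to 42, 35 and 47 without WT_media 2, 4 or 6, and to 55 and 53 without KO_media 4 or 6.

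MHC genes had 2 of 19 with a more negative response in KO (16 adjusted over the list alone), Tap1 (-0.60) and Tapbp (-0.35), at adjusted p = 3.38e-11 and adjusted p = 0.0649 with an estimated correlation. Cholesterol synthesis had 3 of 21 (8 adjusted over the list alone), Insig1 (-0.30), Lss (-0.21) and Nsdhl (-0.25), at adjusted p = 7.81e-10 and adjusted p = 0.0779 with an estimated correlation. Lysosome and phagocytosis had 2 of 28 with a more negative response (13 more negative and 1 more positive adjusted over the list alone), Mertk (-0.48) and Scarb2 (-0.23), which fell further with Pam3 in KO, at adjusted p = 7.81e-10 and adjusted p = 0.0684 with an estimated correlation. Chemokines had 2 of 24, Cxcl16 (-0.41) and Ccl7 (-0.58), with 7 adjusted over the list alone (0.000159, and adjusted p = 0.219 with an estimated correlation). Macrophage identity had Mertk of 25, with 3 adjusted over the list alone (0.00207, and adjusted p = 0.0623 with an estimated correlation). NF-kB targets had 2 of 24, Nfkbie (-0.31) and Icam1 (-0.25), with 4 adjusted over the list alone (0.00830, and adjusted p = 0.351 with an estimated correlation). Glycolysis had Pfkfb3 (0.42) with a more positive response of 21, with 2 more positive adjusted over the list alone (0.0336, and adjusted p = 0.466 with an estimated correlation). Antimicrobial effectors had 0 of 23 called, also adjusted over the list alone, with a median of -0.25 (0.0383, and adjusted p = 0.482 with an estimated correlation). That call ended without KO_media 1, without WT_Pam3 5 and with fry, as did that of glycolysis with fry. All these counts of 3 or fewer changed by more than 1.5 times when single libraries were left out, and without WT_Pam3 5 they were 12 for MHC, 9 for cholesterol synthesis, 9 for lysosome, 5 for chemokines and 3 for macrophage identity. Without WT_Pam3 6 they were 4 for MHC and 4 for chemokines.

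No other list passed for the difference in response, where higher and lower stand for a more positive and a more negative response in KO. Cytokines had Csf1 (-0.52) and Il15 (-0.43) lower of 20, also adjusted over the list alone (0.179). Inflammasome genes had Il1a higher (1 higher and 1 lower adjusted over the list alone, 0.192), and TLR genes had Tlr2 lower (2 adjusted over the list alone, 0.186). Lymphocyte markers had Ighm (-0.47) lower (2 adjusted over the list alone, 0.0612), adhesion genes had Icam1 lower (2 adjusted over the list alone, 0.671), and Secisbp2 (0.21) was the only gene near Ninj1 with a call (1 higher and 1 lower adjusted over the list alone, 0.811, median above 0 and mean below). Apoptosis (0.0923, 6 lower and 1 higher adjusted over the list alone), LXR targets (0.118, 1 lower), the stress list (0.277), NRF2 targets (0.4001, 1 higher), cell cycle (0.700), granulocyte (0.186), dendritic (0.143, 2 lower), mast cell (0.269), erythroid and megakaryocyte (0.766, median below 0 and mean above), stromal (0.624), mitochondrial (0.244) and substrain genes (0.222) had 0 calls over all genes, as did the sex-linked list. Where no count is given, it was also 0 adjusted over the list alone.

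**Figure D4:**
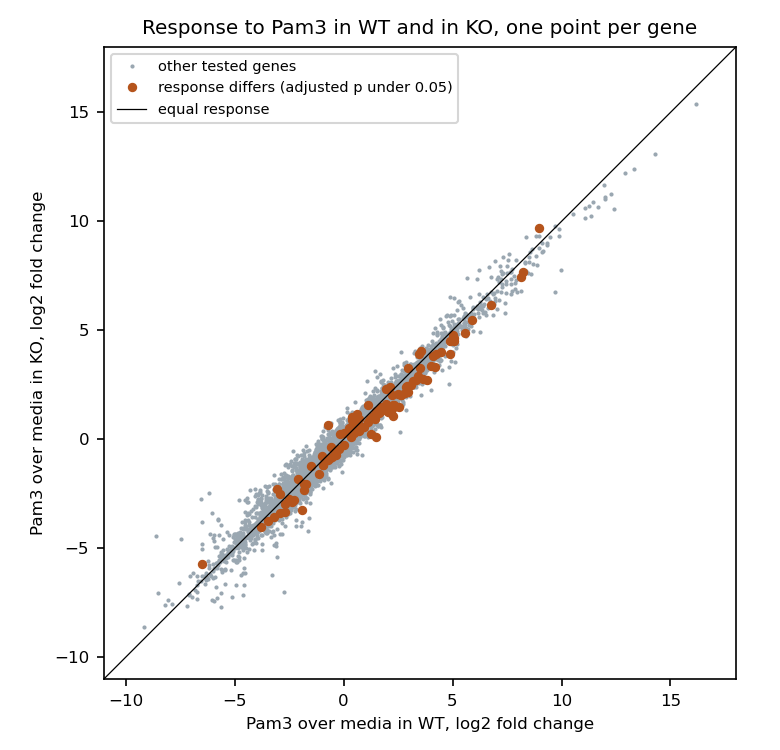
Log2 fold change of Pam3 over media in WT (horizontal) against KO (vertical) for the 14435 tested genes (1 point each), with the 110 genes whose response differed in orange and a diagonal of equal response. Points follow the diagonal closely (slope 0.983), and 85 of the 110 genes had a more negative response in KO.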

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

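Values in this part stood out because 1 library of a group of 6 lay far from the other 5 by the gap to the nearest over the range, or because the Pam3 response differed between genotypes. The tests of splits of the libraries and of length and GC content were written before their results were seen, and all other tests below were chosen after.

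The rule was applied to 197 groups of 6 values, of library measures and of named genes with a mean of at least 1 CPM. Of these, 38 held a library far from the rest, with 15 in WT_Pam3 replicate 5 and 13 in KO_media replicate 1. A rate of about 1 in 20 would give 9.85. That number is no firm baseline, because values of a library vary together and many of the genes were named for large changes. In WT_Pam3 replicate 5 the gap over range was 0.738 for mitochondrial reads (0.336% against a median of 0.448% in the others) and 0.958 for the top 10 genes (12.2% against 9.55%). Among inflammasome genes there it was 0.692 for Nlrp3 (1398 against 1877 CPM), 0.731 for Casp1, 0.729 for Casp4, 0.879 for Pycard (122 against 73.9 CPM) and 0.738 for Gsdmd. It was 0.670 for Ninj1 (1145 against 768 CPM), 0.755 for Xist (233 against 613 CPM), 0.738 for Ptgs2 (1567 against 3114 CPM), 0.661 for Shisa3 and 0.701 for Ifit3. For Kirrel it was 0.714, for Cdh11 0.768 and for Lonrf1 0.686. In KO_media replicate 1 interferon-inducible genes stood high, with 0.722 for Mndal, 0.790 for Ly6a, 0.757 for Tgtp2, 0.783 for Ms4a4c, 0.770 for Ifit3 (167 against 63.0 CPM), 0.732 for Ifi206, 0.757 for Ifit3b and 0.687 for Casp4. Inflammatory genes stood high there too, with 0.914 for Acod1 (16.9 against 3.36 CPM), 0.842 for Il1b (2.68 against 0.760 CPM), 0.765 for Cxcl2 and 0.749 for Tnf (13.5 against 10.2 CPM), while Galnt9 lay low (0.652). In other libraries the gap over range was 0.687 for Mtus2 in KO_Pam3 2, 0.647 for Ninj1 in KO_Pam3 6, 0.713 for Tmem26 in WT_media 4, 0.699 for Trem1 in KO_Pam3 3 and 0.809 for Kif5c in WT_media 2. It was 0.659 for Acod1 and 0.703 for Ifi206 in KO_Pam3 5, 0.658 for BC106179 in KO_media 2, 0.662 for Nlrp3 in WT_media 4 and 0.764 for Pycard in WT_media 1.

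The test of the difference in Pam3 response, KO minus WT, passed for the 31 genes given here. Interferon-inducible genes gave -1.12 for Tgtp2, -1.18 for Ifit3, -1.04 for Ifi206, -0.98 for Ifit3b, -0.79 for Xaf1, -0.75 for Rtp4 and -0.83 for Irf7. Immune receptors, ligands and signalling genes gave -1.35 for Cd101, -0.24 for Tlr2, -0.31 for Nfkbie, -0.25 for Icam1, -0.52 for Csf1, -0.43 for Il15, -0.41 for Cxcl16, -0.58 for Ccl7, -0.47 for Ighm, -0.60 for Tap1 and -0.35 for Tapbp. Metabolic and lysosomal genes gave -0.30 for Insig1, -0.21 for Lss, -0.25 for Nsdhl, -0.48 for Mertk, -0.23 for Scarb2 and 0.42 for Pfkfb3. The remaining genes gave -0.64 for Kif5c, 0.78 for Dio2, 0.76 for Gpr155, 0.73 for Il1a, 0.67 for Rims3, 0.55 for Lonrf1 and 0.21 for Secisbp2. Camera adjusted p of the 9 lists with a differing response were 3.00e-27 for interferon-stimulated genes, 3.38e-11 for MHC genes, 7.81e-10 for cholesterol synthesis and for lysosome genes, 0.000159 for chemokines, 0.00207 for macrophage identity, 0.00830 for NF-kB targets, 0.0336 for glycolysis and 0.0383 for antimicrobial effectors. None of the 9 passed with an estimated correlation (adjusted p = 0.0623 to 0.482).

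For each comparison, 100 splits of its libraries were called as the real one was, and only 1, the real split, called as many genes. The real counts and the highest of the others were 438 and 1 in media, 586 and 189 after Pam3, 12235 and 10202 for Pam3 in WT, 12273 and 10057 for Pam3 in KO, and 110 and 1 for the interaction. For Pam3 against media this outcome was all but fixed, because treatment dominated the data. The splits treat libraries as exchangeable, so they cannot tell genotype from a difference between animals or cultures.

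WT_Pam3 replicate 5 lay away from its group. The trend fitted on exon length and GC content is excluded as the whole cause. Removing that trend left a deviation of 0.462 (root mean square, log2, from 0.552) against at most 0.288 in the other 23 libraries. A length or GC bias that the fitted trend does not capture was not tested. The Spearman correlation of this library's deviation from its group mean with exon length was -0.484 (-0.312 to 0.285 in the other libraries). A KO or an unstimulated library under a wrong label is excluded, since Ninj1 stood at 1145 CPM (at most 479 CPM in KO_Pam3) and Tnf at 7568 CPM (at most 13.5 CPM in media libraries). Other kinds of wrong label were not tested. Whether RNA of megakaryocytes or their precursors was present is undecided. The erythroid and megakaryocyte markers lay at percentile 99.83 among random lists matched on expression, with Pf4 at 178.9 CPM against 97.63 to 110.4 CPM. Itga2b, Gp9, Ppbp and Gata1 lay above the others too, and Car2 within their range. The lists were not matched on gene length or GC content, whose trend took 30% of the variance of this deviation. The percentile therefore cannot tell RNA of other cells from that bias. Erythroid RNA rich in haemoglobin transcripts is excluded by a haemoglobin sum of 0.109 CPM (0.0327 to 0.185 CPM in the others). Erythroid cells with little haemoglobin RNA were not tested. Stromal markers lay at percentile 0.08 of the same kind of random lists, with the same limit. No further biological explanation was tested, because the labels give this library nothing of its own.

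Interferon-stimulated genes were higher in KO_media, with a set call that did not pass with an estimated correlation. A single library is excluded as the cause, since 24 of the 27 called members stayed called without KO_media replicate 1. Genotype and culture, animal or batch cannot be told apart here, because the labels give 1 set of libraries per genotype and no batch.

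Granulocyte markers and, with the preset correlation only, stromal markers were higher as lists in KO_media. A rise of the markers of all other cells alike, as a lower share of macrophages could give, was not seen. The granulocyte score rose by 0.244 and the lymphocyte score shifted by -0.0863. The exact permutation p for the difference between these shifts was 0.00217, the smallest possible. This p is no independent support, because the granulocyte list was chosen after its rise in these libraries was seen. How much lymphocyte RNA the cultures held was not measured, so a lower share of macrophages cannot be excluded. Granulocyte RNA in the KO libraries is undecided, because the profile of such cells was not measured, with S100a8 (0.51), S100a9 (0.50), Ltf (0.53) and Camp (0.47) near Ngp (0.54) and 6 of 11 markers over 2 SE from it, namely Mpo (0.11), Elane (0.15), Prtn3 (0.07), Csf3r (0.03), Mmp8 (-0.09) and Mmp9 (0.20). Stromal RNA in some KO libraries is also undecided, with a span of the stromal score 2.525 times as large over KO_media as over WT_media libraries (0.725 against 0.287). Genotype as a cause could not be separated from differences between cultures.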

How the results depend on the processing

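Of 137 pairs of a comparison and a gene that was always named or ranked among its largest changes, 97 passed the test, and 83 of those passed under every setting other than a stricter threshold. Calls ended 158 times when a library was left out, 96 times under a stricter threshold, 4 times with limma-voom, 3 with no filter, 2 each with DESeq2 size factors, library size only and the 12 libraries compared, and 1 each with upper-quartile scaling and at least 50 counts. Calls were also gained 21 times, with the same sign, by pairs that did not pass in the main fit. A missing call of a named gene is therefore not always stable. A further 86 sign changes, in 15 of the 137 pairs, passed in neither fit. Pycard with Pam3 in WT (-0.39) and Xist with Pam3 in KO (-0.43) passed with library size only, while both lay above 0 with TMM and did not pass. Of 293 further calls, of Gpr137b and of list members with the smallest adjusted p, 227 kept call and direction under every setting other than a stricter threshold. Those that did not were 14 of 46 in media, 30 of 47 after Pam3 (27 of them with the 12 libraries compared), 3 of 91 with Pam3 in WT, 4 of 90 in KO and 15 of 19 for the interaction. Called rises with Pam3 turned into called falls with library size only for Spp1 (-0.33 in WT and -0.30 in KO) and for mt-Nd1 in KO (-0.32), and changed sign without passing for Ppbp in KO (-0.0664) and, with upper-quartile scaling, for Spp1 in WT (-0.0015) and mt-Nd1 in KO (-0.0174). Of 57 set calls an estimated correlation ended 48, fry 5, KO_media replicate 1 left out 3, WT_Pam3 replicate 5 left out 3, and the scalings 1 each. Set calls were gained too, 25 with fry, 10 without WT_Pam3 replicate 5, 5 with library size only, 4 without KO_media replicate 1 and 3 with upper-quartile scaling. The slope stayed within its jackknife SE in all 27 alternatives. Of these, 24 were the fits with a library left out, which gave that SE and so could hardly lie far beyond it. The others were the genes called in WT, at least 50 counts on average and DESeq2 size factors. The slope was not computed with the other scalings or tests. With thinned counts the differences in detected genes kept their direction, at 170 in place of 260 for KO_Pam3 minus WT_Pam3, -130 in place of -190 for KO_media minus WT_media, -1410 in place of -1480 with Pam3 in WT and -1110 in place of -1030 in KO. No paired analysis was possible because replicate numbers pair nothing, and a Y-linked covariate was not fitted.

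Counts of genes moved more, and the cause was not tested unless the setting's construction gives it. With library size only, 412 rose and 220 fell in KO_Pam3 against WT_Pam3, 3584 rose with Pam3 in WT and 3685 in KO, and 54 responses were more negative. With no filter 183 fell in KO_Pam3 and 41 responses were more negative. DESeq2 gave 271 lower in KO_media, 599 lower in KO_Pam3 and 85 and 302 differing responses. With glmTreat at 2-fold 2 rose and 0 fell in KO_media, 0 and 0 in KO_Pam3, 2253 and 3115 with Pam3 in WT, 2227 and 3120 in KO, and 0 and 0 responses differed, beside 1872, 2354 and 1768 genes with an unadjusted edgeR p under 0.05 between genotypes in media, after Pam3 and in the interaction. At 2-fold or more edgeR called 11 and 5, 11 and 4, 2621 and 3628, 2583 and 3645, and 1 and 6 in the same order. At an adjusted p under 0.01 there were 106 and 54 in media, 56 and 181 after Pam3 and 1 and 6 differing responses. With 1 surrogate variable there were 644 and 548, 422 and 861, and 132 and 498. That variable was 0.919 in WT_Pam3 replicate 5 and -0.191 to 0.0705 in the other libraries. This setting therefore nearly repeats leaving out WT_Pam3 replicate 5 and is not a separate check. With only the 12 libraries compared there were 581 and 531 in media and 63 and 114 after Pam3. With WT_Pam3 replicate 5 and KO_media replicate 1 both left out, chosen after seeing the data, there were 541 and 515, 389 and 936, and 91 and 411. With single libraries left out the counts ran from 154 to 658 higher and 84 to 616 lower in media, 106 to 352 and 267 to 826 after Pam3, 5755 to 5981 and 6352 to 6651 for Pam3 in WT, 5744 to 6040 and 6395 to 6733 in KO, and 8 to 102 and 20 to 442 for the interaction. Depth limits genes near 0 counts, and for groups at 0 counts folds are given as lower bounds.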

Other observations

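Some genes split libraries within groups along lines that the labels do not give, which is reported as values with no test. The libraries of a group may therefore not be independent replicates. In that case the p-values between genotypes, which count 6 libraries per group, would be too small. Mndal stood at 24.1 to 30.9 CPM in WT_media 1, 2 and 5 and at 43.0 to 48.5 CPM in WT_media 3, 4 and 6. In KO_Pam3 1, 3 and 4 Capn11, Cdh11 (5.69 to 6.12 CPM) and Kirrel (2.20 to 2.44 CPM) were higher than in KO_Pam3 2, 5 and 6 (Cdh11 3.86 to 4.18 CPM, Kirrel 1.38 to 1.60 CPM).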
